A study of Mus musculus with 2 samples.

How the data were processed

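Small RNA libraries from mouse embryonic heart (2 libraries, 1 group, embryonic day 14.5) were analysed from the read count table deposited for each. Per the deposited descriptions, the counts refer to genome build mm10 and the GENCODE M4 annotation, with 1 table per library and no pooling of replicates. The aligner, the counting program and their versions are not given in the sources used here. Per the labels, the size range of the libraries lay below 30, with no unit given. The deposited tables hold whole-number counts in 3 columns, both strands together and each strand alone, for 1973 miRNA genes and 4 further lines for reads assigned to no gene. The strands added up to the unstranded count for every gene, and both tables matched the checksums listed with them. The counts were not normalized by the authors, as judged from their being whole numbers with different totals per library.

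No description names the strand to use, so the strand-specific column with the larger total was taken, a choice made before the data were examined. It held 95.4% ± 0.103 (SD, n = 2) of the gene reads. Of all reads, 53.0% ± 0.191 were assigned to genes on that strand, 30.4% ± 0.359 mapped to several places, 11.9% ± 0.330 did not map and 4.73% ± 0.220 were assigned to no gene on that strand, a class that includes reads on the opposite strand of a gene. Lines that name no gene were left out of totals. A layout of this kind keeps reads mapping to several places out of the gene counts, so miRNAs made by near-identical loci can be under-counted. Per library, 3 counts correspond to 0.693 CPM in replicate 1 and 0.781 CPM in replicate 2. All intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

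Gene symbols, coordinates and overlapping genes came from GENCODE M21, which uses the same mouse assembly as mm10, and 1894 of 1973 identifiers were named. The other 79 had at most 1 count. M21 lists 2207 miRNA genes, of which 313 have no entry in the tables. Near-identical loci were defined by a copy number in the symbol and by shared stretches of 20 or 18 bases between annotated hairpins. A search of the whole genome sequence was not made.

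Counts were scaled to the total on genes of the counted strand (CPM), and log2 values used a pseudocount of 1 CPM. A gene was called detected with at least 10 counts in each library. The 28 lists of miRNA families and cell type markers, the 32 clusters of shared transcripts, of which 30 had at least 2 measured members, and the rule for named genes were fixed before the data were examined. The rule took the 25 most abundant genes, all members of the muscle list, the 2 most abundant members of every other list, the highest and lowest members of clusters, and the 5 genes with the largest ratio between replicates in each direction among those with a mean of at least 100 CPM. Mir205, Mir200c, Mir7b, Mir199b, Mir199a-1, Mir145b, Mir122, Mir31, Mir34c, Mir224, Mir449a, Mir184, Mir296, Mir298, the copies of miR-124 and miR-9, and the miRNAs named for reads on the opposite strand were chosen after their values were seen, as were the ratios between pairs of genes. List levels were set against 10000 random lists of all genes, with Benjamini-Hochberg adjustment over the 28 lists, and list ratios between replicates against 10000 random lists matched on mean level, drawn from the 50 genes nearest each member. Comparisons across genes describe these 2 libraries and not animals. The labels number the libraries as separate biological replicates, and any spread between them includes the difference in collection day.

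The biological coefficient of variation was estimated with edgeR 4.0.16 (common dispersion, R 4.3.3), and DESeq2 1.42.0 gave the median-of-ratios size factors. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Counts simulated from the 2 heart libraries over 396 genes with dispersions of 0.005, 0.02 and 0.05 returned 0.00522, 0.0205 and 0.0493. In a separate simulation 200 of the more abundant genes were changed by a log2 ratio of 1, at a dispersion below the 0.0398 estimated from the libraries. Their median lay 0.96 above that of the unchanged genes, a difference that does not test for a shift in scale. A simulated list of 10 genes changed by 1 was returned at 1.06 and percentile 100. A simulated list left unchanged gave a median of 0.27 at percentile 74.1, and 6 of 200 further unchanged lists of 10 genes (3%) fell outside the central 95%. The alternatives were the unstranded column, TMM and median-of-ratios scaling, pseudocounts of 0.1 and 10 CPM, other count minimums, a total without the most abundant gene, thinning of the deeper library, and each replicate left out. Alternatives added after the data were seen were counting reads on the opposite strand under the gene they face, comparing copies within clusters and among genes with an annotated hairpin, and limiting the epithelial list to members with at least 100 counts.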

Results

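The series profiled microRNAs (miRNAs) in hearts of mouse embryos of the strain B6NCrl at embryonic day 14.5 by small RNA sequencing. It holds 1 group of 2 libraries, labelled as biological replicates 1 and 2 and collected on 15 and 17 July 2014. There is no treated or control group, so the series describes which miRNAs an embryonic heart holds and how far 2 libraries differ. Each library is described as a single heart, while the sex entry names males and females pooled, and the labels do not settle which holds. Replicate 1 held 8150499 reads and replicate 2 held 7269505, of which 4327424 and 3839984 were assigned to miRNA genes on the counted strand. With 1 group there is no difference between groups to test, so values are given as mean ± SD of CPM (counts scaled to the assigned reads of each library).

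Few miRNAs made up most of the assigned counts. Ranks and shares here cover only reads assigned to genes on the counted strand. The 30.4% ± 0.359 of all reads that mapped to several places are left out, as are opposite-strand reads such as those facing Mir378a. Mir335 was the most abundant, at 119648 ± 7637 CPM (SD, n = 2), followed by Mir143 at 74458 ± 15820, Mir126a at 72473 ± 3594, Mir322 at 69474 ± 3573 and the cardiac miRNA Mir208b at 66568 ± 359. Mir335 lay above all other miRNAs in both libraries, and Mir208b lay below Mir126a and Mir322 in both, while Mir143 was the lowest of these 4 in replicate 1 and the highest in replicate 2. Mir126a lay above Mir322 within each library, although their ranges over the libraries overlapped. Mir335 (chromosome 6, 30741299 to 30741396, mouse build mm10) lies in an intron of Mest, an imprinted gene. Mir143 lies on chromosome 18 (61649196 to 61649258) outside other annotated genes, and Mir322 on the X chromosome (53054255 to 53054349). Mir126a, on chromosome 2 (26591357 to 26591429), lies within the endothelial gene Egfl7. There it overlaps an exon of at least 1 annotated transcript of Egfl7, and also an intron of Gm20532. Next came Mir99a at 57680 ± 2169 CPM, Mirlet7g at 41466 ± 2860, Mirlet7i at 37535 ± 4115, Mir26b at 33998 ± 382 and Mir30e at 33910 ± 3920. The single most abundant gene took 11.96% ± 0.764 of the counts, the top 5 took 40.3% ± 1.57, the top 10 took 60.7% ± 0.660 and the top 20 took 78.6% ± 0.412. Of the counts, 90% lay in 44 genes in replicate 1 and 46 in replicate 2. Of the top 25, 12 lie in an intron of another gene on the same strand. Among them are Mir126a in Gm20532, Mirlet7g in Wdr82, Mir26b in Ctdsp1, Mir30e in Nfyc and Mir483 in Igf2. In all, 337 of 1973 genes had at least 10 counts in each library, 542 had at least 1 count in each, and 78 exceeded 1000 CPM.

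**Figure D1:**
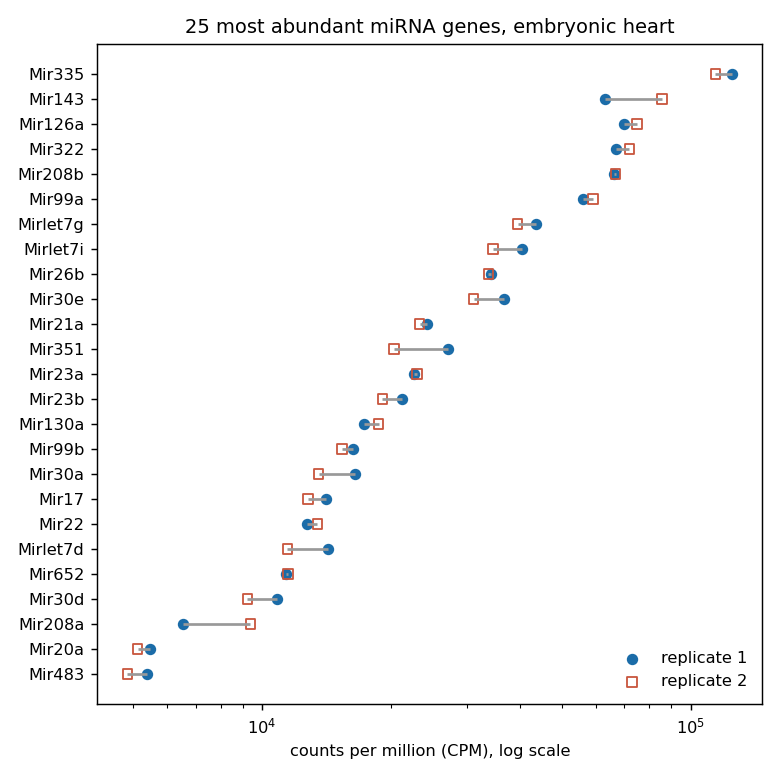
Level of the 25 most abundant miRNA genes in CPM (log axis) in embryonic heart, with 1 point per library (n = 2) and a line joining the replicates. Mir335 stands highest in both libraries, and Mir143, Mir351 and Mir208a show wide gaps between replicates.

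Among reads assigned to genes, the heart muscle miRNAs were represented almost entirely by those hosted in myosin genes. Mir208b, in an intron of Myh7 (chromosome 14, 54975700 to 54975776), exceeded Mir208a, in an intron of Myh6 (chromosome 14, 54949060 to 54949142), in both libraries. The ratio was 10.1 in replicate 1 and 7.12 in replicate 2, with Mir208a at 7962 ± 2009 CPM. Myh7 encodes the beta and Myh6 the alpha cardiac myosin heavy chain. Mir499, in an intron of Myh7b (chromosome 2, 155622880 to 155622958), reached 3023 ± 179 CPM, so that Mir208b lay 22.1 ± 1.18 times above it. Together these 3 miRNAs held 7.76% ± 0.255 of all counts and 99.95% ± 0.0163 of the muscle list. Mir206, a miRNA of skeletal muscle, had 68 and 131 counts, or 24.9 ± 13.0 CPM. The other listed members were near the limit of detection, with 12 counts of Mir133a-1 in each library, 13 and 10 of Mir1a-1, 9 and 15 of Mir133b, 11 and 4 of Mir1b, and 2 and 5 of Mir133a-2. These 5 genes summed to 11.4 ± 0.791 CPM. Each of the 5 shares a stretch of 20 bases with another miRNA hairpin, and reads mapping to several places are counted apart from the genes. Their levels are therefore uncertain, and the share of 99.95% for the myosin-hosted miRNAs can be too high. Mir1a-2 has no entry in the tables.

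Mir143, Mir126a and Mir21a, which led the smooth muscle, endothelial, and fibroblast and mesenchymal lists, were abundant. Which cells of the heart their reads came from was not measured. The endothelial list was carried by Mir126a, since Mir126b has no entry. In the smooth muscle list, summing to 75796 ± 15984 CPM, Mir143 stood 55.3 ± 5.05 times above Mir145a (1338 ± 164 CPM) of the same transcript. Mir143 was 63272 CPM in replicate 1 and 85644 in replicate 2, the widest gap in CPM among the top 5. The fibroblast and mesenchymal list summed to 27612 ± 518 CPM, of which Mir21a gave 23749 ± 622 and Mir214 gave 3621 ± 118. Its other members were lower, Mir199b at 193 ± 21.6 CPM, Mir199a-2 at 46.5 ± 6.35 and Mir199a-1 at 2.85 ± 0.760, and all 3 share 20 bases with another hairpin. Mir145b of the smooth muscle list had 0 counts. Among assigned reads, the summed levels of the smooth muscle, endothelial and muscle lists (77589 ± 2560 CPM) differed little. The muscle list lay above the endothelial list in both libraries, and the smooth muscle list overlapped both. All 3 lay above the fibroblast list in both libraries. In the muscle list 5 of 9 measured members share 20 bases with another hairpin, as do 3 of 5 in the fibroblast list. Both sums can be under-counted, so the order of these lists is uncertain. The miR-29 family summed to 356 ± 59.8 CPM, with Mir29a at 254 ± 39.2, and 3 of its 4 members share 20 bases with another hairpin, so its level is uncertain.

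**Figure D2:**
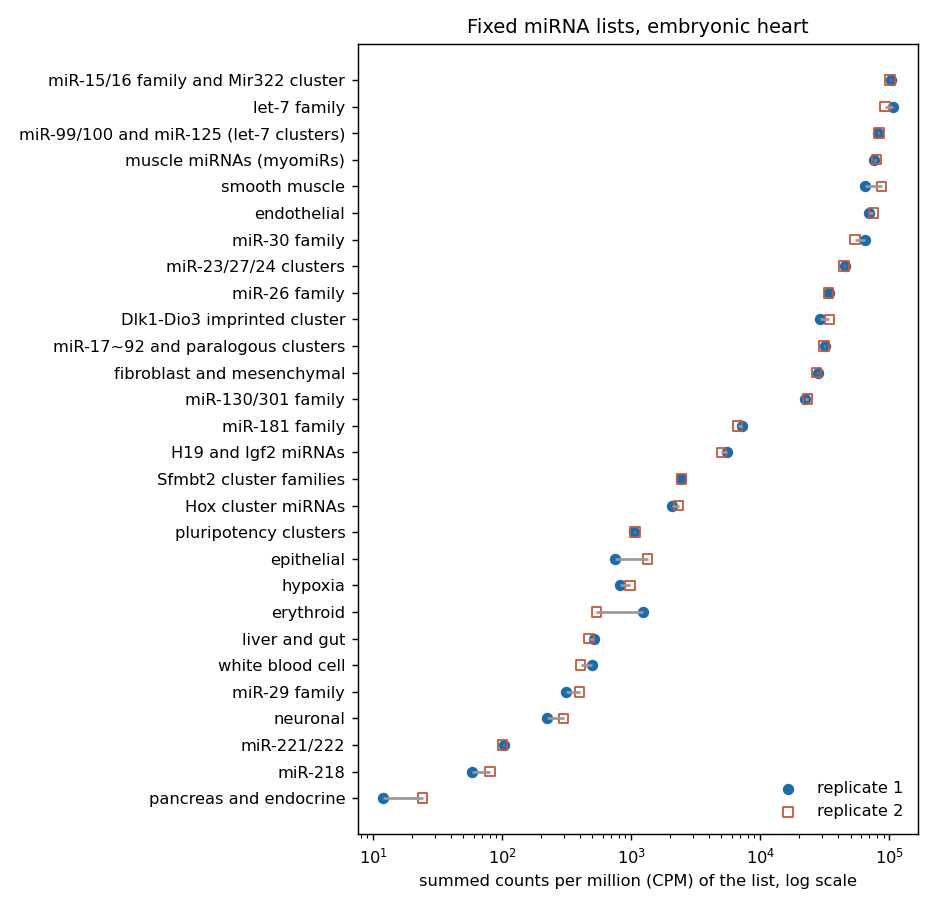
Summed CPM (log axis) of each miRNA list fixed beforehand, with 1 point per library (n = 2) and a line joining the replicates. The let-7 family and the miR-15/16 family with the Mir322 cluster are the highest lists, and the erythroid, pancreas and endocrine, and epithelial lists show the widest gaps between replicates.

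Broadly expressed families filled much of the remainder. The miR-15/16 family with the Mir322 cluster summed to 102343 ± 1258 CPM, with Mir322 leading and Mir351 at 23746 ± 4861, and the let-7 family summed to 99521 ± 9957. Of the 14 let-7 members 10 have an entry, all of them detected, and Mirlet7e and Mirlet7f-1 are among those without one. With opposite-strand reads added, the sums were 98075 CPM for the miR-15/16 list and 99603 for let-7, so their order is uncertain. The miR-99/100 and miR-125 miRNAs reached 82075 ± 1446 CPM, led by Mir99a and by Mir99b at 15813 ± 665. The miR-30 family summed to 59326 ± 7071, with Mir30a at 14990 ± 2038 and Mir30d at 10035 ± 1130, and the miR-23/27/24 clusters to 45028 ± 657, nearly all of it Mir23a (22764 ± 282) and Mir23b (20120 ± 1464). Mir26b gave almost all of the miR-26 family (34045 ± 386 CPM), at 927 ± 120 times the level of Mir26a-2. The miR-17~92 and paralogous clusters, which are linked to cell proliferation, summed to 31460 ± 440 CPM with 14 of 15 members detected, led by Mir17 (13435 ± 897) and Mir20a (5292 ± 239). Mir130 and Mir301 miRNAs summed to 22767 ± 666 CPM, led by Mir130a (18001 ± 979) and Mir130b (3413 ± 243), and the miR-181 family to 6927 ± 369, led by Mir181c (2719 ± 6.5) and Mir181d (2359 ± 123). Lower were the Hox cluster miRNAs at 2200 ± 175 CPM, with Mir10a at 1243 ± 368 and Mir10b at 834 ± 185, the hypoxia miRNA Mir210 at 896 ± 111, the Mir221 and Mir222 pair at 102 ± 1.12 and miR-218 at 69.5 ± 15.2. Mir221 reached 68.0 ± 1.53 CPM and Mir222 33.6 ± 0.409, and Mir218-2, in an intron of Slit3, reached 48.9 ± 12.6 against 20.6 ± 2.60 for Mir218-1, in an intron of Slit2. Mir26a-2 and both miR-218 genes share 20 bases with another hairpin, as Mir23a and Mir23b do, so their levels are uncertain. The same holds for 5 of 10 measured let-7 members, 4 of 6 of the miR-181 family and 4 of 15 of the miR-17~92 clusters. It also holds for 2 of 6 of the miR-30 family, 2 of 6 miR-99/100 and miR-125 miRNAs and 2 of 8 of the miR-15/16 list. In the miR-23/27/24 clusters it holds for 5 of 5, and for Hox miRNAs for 2 of 6. The sums and leading members of these lists are therefore uncertain.

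Markers of other cell types and neighbouring tissues lay far below the muscle, smooth muscle and endothelial lists. The erythroid list summed to 891 ± 499 CPM and was mostly Mir451a (753 ± 477), ahead of Mir144 (84.0 ± 14.6) from the same locus. The white blood cell list summed to 449 ± 62.2 CPM, with Mir223 at 318 ± 39.0 and Mir155 at 116 ± 25, and summed to 1113 once reads on the opposite strand of an entry facing Mir142 were added. The epithelial list gave 1046 ± 414 CPM with all 10 members detected, led by Mir429 (381 ± 126) and Mir203 (243 ± 28.6). Liver and gut miRNAs gave 494 ± 33.4 CPM, led by Mir215 (302 ± 41.7), with Mir192 at 54.6 ± 6.69. Neuronal miRNAs gave 260 ± 55.0 CPM, led by Mir128-1 (115 ± 9.02) and Mir137 (49.4 ± 51.3), with 7 of 14 measured members detected. Of the 14, 11 share 20 bases with another hairpin, Mir128-1 among them. Pancreas and endocrine miRNAs gave 18.1 ± 8.63 CPM, nearly all Mir375 (17.3 ± 8.38), while Mir217 had 1 and 2 counts. Pluripotency miRNAs gave 1055 ± 18.8 CPM, led by Mir302a (391 ± 0.955) and Mir302d (336 ± 10.5), and Mir302a shares 20 bases with another hairpin. All 5 measured copies of miR-124 and miR-9 had 0 counts. For assigned reads this allows up to 0.693 CPM in replicate 1 and 0.781 in replicate 2. All 5 share 20-base stretches with other hairpins, so the count of 0 sets no limit on reads that mapped to several places.

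The lists of imprinted loci differed in level. The Dlk1-Dio3 cluster summed to 31485 ± 3854 CPM, with 38 of 46 measured members detected, led by Mir487b (4830 ± 4.28) and Mir411 (4394 ± 874), both of which share 20 bases with another hairpin. Mir483, in an intron of Igf2, reached 5116 ± 382 CPM and Mir675, in an exon of H19, reached 131 ± 20.8. The Sfmbt2 cluster families summed to 2441 ± 6.36 CPM, led by Mir467e (781 ± 30.4) and Mir467d (673 ± 48.2), with 9 of 69 genes detected, and 67 of the 69 share a 20-base stretch with another hairpin. Against 10000 random lists of the same size from all 1973 genes, 20 of the 28 lists had a higher median level at a Benjamini-Hochberg adjusted resampling p of at most 0.05 over the 28 lists, and 0 had a lower one. The muscle list had an adjusted p of 0.0261 and the Sfmbt2 list did not pass. Most genes in the tables, 1285, had 0 counts in both libraries, and among detected genes only, 0 of the 28 lists passed, with a lowest adjusted p of 0.149.

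miRNAs of the same primary transcript differed widely in level. Mir17 exceeded Mir19b-1 by 10.40 ± 0.27 on the log2(CPM + 1) scale, and Mir99a exceeded Mirlet7c-1 by 9.10 ± 0.20. Mir30e stood 299 ± 50.2 times above Mir30c-1, Mir214 stood 78.3 ± 8.15 times above Mir199a-2, and Mir322 stood 23.3 ± 0.409 times above Mir503. In these pairs, except the last, the lower member shares a 20-base stretch with another hairpin and its level is uncertain. Other neighbours were close, as Mir181c and Mir181d, which differed by 0.21 ± 0.07, and Mir15a and Mir16-1, which differed by 0.39 ± 0.26, although Mir16-1 shares 20 bases with another hairpin. Mir302a lay at least 499-fold above Mir367, which had 0 counts, taking 3 counts per library as the floor. Over 30 clusters the median difference between highest and lowest member was 4.29, and it stayed 4.29 with Mir367 set at the floor. In 17 of the 30 it exceeded 10-fold, and in 12 of these 17 the lowest member shares a 20-base stretch with another hairpin. The same holds for 19 of all 30 clusters.

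Genes with a copy number in their symbol, such as Mir1a-1 and Mir133a-1, were compared with the rest. The 118 such genes were detected more often, 35.6% against 15.9%, with a median log2(CPM + 1) higher by 0.17 (permutation test across genes, two-sided, p = 1e-05, the smallest that 100000 permutations can give). Without replicate 2 that difference was 0. The medians were 0.17 for such genes and 0 for the rest. Both lie below the floor of 0.693 CPM in replicate 1 and 0.781 in replicate 2. A gene with 1 read in replicate 2 and 0 in replicate 1 had 0.260 CPM in replicate 2. The median difference is therefore of the size of a single read in 1 library. Within 14 shared-transcript clusters, a comparison chosen after the data were seen, the direction turned by the same symbol definition: such genes lay below their neighbours in 14 of 14 clusters, by a mean of -4.58 (permutation test within clusters, two-sided, p = 0.00022). It turned also by the sequence definition over the 1894 genes with an annotated hairpin. Of the 929 genes whose hairpin shares 20 bases with another, 8.18% were detected, against 27.05% of the other 965. The median difference was -0.17 (permutation test, p = 1e-05, the smallest possible). The medians were 0 and 0.17, so this difference too is of the size of a single read.

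The 2 libraries gave closely similar profiles. Across 396 genes with a summed count of at least 10, log2(CPM + 1) values had a Pearson r of 0.992 and a Spearman rho of 0.986, across genes, which are not independent replicates. The median absolute log2 ratio was 0.24, against 0.16 with a pseudocount of 10 CPM and 0 with no filter on low counts, and the biological coefficient of variation was 19.96%. The labels number the libraries as separate biological replicates, and their totals and counts differ (chi-square 46024.9 on 395 degrees of freedom, against counting noise alone), which does not show whether they come from separate animals. Of 170 genes with a mean of at least 100 CPM, only Mir451a, a red blood cell miRNA, differed by more than 2-fold, with 1090 CPM in replicate 1 and 415 in replicate 2 (2.62-fold lower, 95% counting interval 2.48 to 2.78). Next among those lower in replicate 2 were Mirlet7a-2 (1.55-fold), Mirlet7f-2 (1.5-fold), Mir505 (1.43-fold) and Mir501 (1.42-fold), and the let-7 genes among them share 20 bases with another hairpin. Higher in replicate 2 were Mir200b (1.73-fold, interval 1.51 to 1.97), Mir429 (1.61-fold, 1.5 to 1.73), Mir10a (1.53-fold), Mir154 (1.51-fold) and Mir341 (1.51-fold).

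Of the 28 lists, 4 had a median log2 ratio of replicate 2 to replicate 1 outside the central 95% of 10000 random lists matched on mean level. If list members varied independently, 1.4 would be expected outside. Members of the epithelial, let-7, erythroid and Dlk1-Dio3 lists partly share transcripts or a locus, whereas random members were drawn independently. The value of 1.4 can therefore be too low, and the percentiles too extreme, for these 4 lists. The epithelial list was higher in replicate 2 for 10 of 10 members, with a median of 1.15 (percentile 100). Mir205 had 51 and 360 counts (7.95-fold, 5.92 to 10.9) and Mir200c had 153 and 456 (3.36-fold, 2.79 to 4.06). Single markers of other tissues were also higher in replicate 2, among them the neuronal Mir137 with 57 and 329 counts (6.50-fold, 4.90 to 8.78), Mir7b with 12 and 45 (4.23-fold), Mir206 (2.17-fold) and the endocrine Mir375 (2.05-fold). Others were lower, and the neuronal list had a median of 0.09 at percentile 46.1, with 5 of 7 compared members higher and 2 lower. The liver and gut list lay at percentile 49.3, with 3 of 5 members higher and 2 lower. The let-7 family was lower for 10 of 10 members, with a median of -0.23 (percentile 0.84), and the erythroid list for 3 of 3, with a median of -0.35 (percentile 1.89). The Dlk1-Dio3 list was higher for 32 of 38 members, with a median of 0.22 (percentile 99.6), and for 28 of 38 with a median of 0.11 under median-of-ratios scaling. That scaling moved the median of all genes from 0.08 to -0.03, a shift of -0.11. With both strands counted the erythroid list fell inside the range (percentile 3.29) and the white blood cell list outside it (-0.32, percentile 0.83), as the latter also did with a pseudocount of 10 CPM (percentile 2.33). With no filter on low counts the Hox (percentile 99.9) and smooth muscle (percentile 97.9) lists also lay outside. Replicate and collection day cannot be told apart, so these are differences between 2 libraries.

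**Figure D3:**
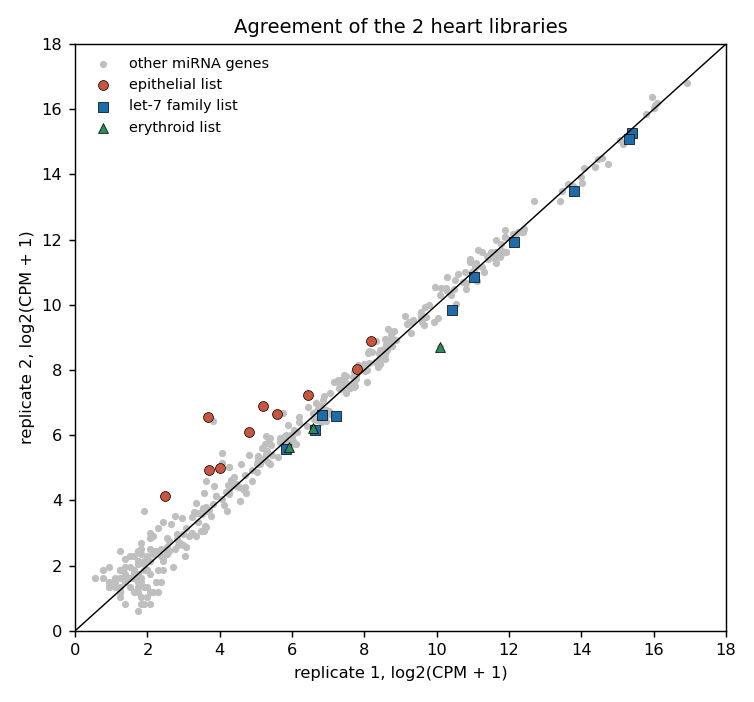
Level of each miRNA gene, as log2(CPM + 1), in replicate 1 (horizontal axis) and replicate 2 (vertical axis) for 396 genes, with 1 point per gene and the line of equality. The 10 epithelial members lie above the line, and the let-7 and erythroid members lie below it.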

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

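Both tests of reads on the opposite strand were chosen after the result was seen. At 10 genes the strand left out of the main counts held at least 100 reads in each library, and more than the counted strand. These genes had at most 2 reads per library on the counted strand. Genes with fewer opposite-strand reads were not examined here. The largest signal, 287973 reads over both libraries, was at Gm25301 (chromosome 18, 61397813 to 61397925), which faces Mir378a and lies within an intron of Ppargc1b, a coactivator of mitochondrial metabolism. That equals 35207 ± 1218 CPM of the counted strand (SD, n = 2) and would rank 9 among all miRNAs. Reads facing Mirlet7e numbered 39454, or 4813 ± 418 CPM. Those facing Mir191 numbered 19827, and those facing Mir142, a miRNA of blood cells, numbered 5915, or 718 ± 137 CPM. In the Dlk1-Dio3 region, reads numbered 17702 facing Mir409, 9614 facing Mir376a, 8205 facing Mir299a and 4142 facing Mir380. Reads facing Mir497 numbered 4136 and those facing Mirlet7f-1 numbered 1011.

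A leak of reads to the wrong strand would put reads on both strands of abundant genes alike, but the 100 most abundant genes had only 0.000838% of their reads on the opposite strand. All 10 of the genes lie opposite an annotated miRNA gene that has no entry of its own in the tables, against 22 of the 1963 others (1.12%). The opposite-strand reads are therefore consistent with reads of those miRNAs, and Mir378a may belong among the 10 most abundant miRNAs of these libraries. No biological explanation was tested, since the design has 1 group.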

How the results depend on the processing

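Leaving out a replicate gives the value of a single library, always within 1 SD of a mean of 2, so it says nothing about stability for means. For copies of a mature sequence the 2 single-library values ranged from 0 to 0.17. Counting both strands moved the share of the top 10 genes to 58.1% and the muscle list to 73995 CPM, and adding opposite-strand reads (chosen after seeing the data) gave the muscle list 73989 CPM. Leaving out Mir335 gave 58.2% for the top 10 genes, which then take in the next gene, and 88125, 113101 and 82309 CPM for the muscle, let-7 and endothelial lists, by the smaller total alone. A minimum of 1 count gave 542 detected genes. Pearson r was 0.995 with a pseudocount of 10 CPM and 0.996 with no filter on low counts, and the median absolute log2 ratio was 0.16 and 0, since genes at 0 in both libraries then count as equal. Among detected genes only, 0 lists lay above random lists. Median-of-ratios scaling moved the Dlk1-Dio3 median to 0.11. Among detected genes the strand share was 99.99%. Copies of a mature sequence turned to -0.15 by shared 20-mers and by shared 18-mers, and to -3.88 and -4.58 within clusters (chosen after seeing the data) by 20-mers and by symbol, and the cause was not tested. Among genes with an annotated hairpin (chosen after seeing the data) it was -0.17 by 20-mers and -0.27 by 18-mers. Except within clusters, these differences compare medians below 0.693 CPM, so their size reflects very few reads. With both libraries kept, 71 of 110 values for the other 22 lists moved by less than 1 SD and 39 by more, which depends mainly on how small each SD is, since most of these shifts follow the total and are alike between lists. The epithelial median log2 ratio stayed between 0.85 and 1.19 under the 7 settings fixed before the data were seen. No paired analysis was possible because the series has only 1 group. Depth limits single genes below about 0.693 to 0.781 CPM.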

Other observations

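The test of library scaling and that of a further epithelial list were set before their results were seen, and all other tests and the imprinted loci and chromosomes described here were chosen after. Of the imprinted loci, Mest, Dlk1-Dio3, Igf2 with H19, the Gnas region and the Sfmbt2 intron together held 16.5% ± 0.474 of the counts (SD, n = 2), most of it from Mir335. Mir335 of Mest alone gave 11.96% ± 0.764 and the Dlk1-Dio3 list gave 3.15% ± 0.385. Mir296 and Mir298 of the Gnas region gave 0.625% ± 0.0600, above the 0.525% ± 0.0361 of Mir483 and Mir675. In the Sfmbt2 intron 9 of 107 genes were detected, with 0.244% ± 0.000543 of the counts.

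The X chromosome held 12.9% ± 0.155 of the counts from 37 detected genes, led by Mir322, Mir351 and Mir652 (11425 ± 75.3 CPM), the last in an intron of Tmem164. Chromosome 6, where Mir335 lies, held 12.2% ± 0.747, and chromosome 12, with the Dlk1-Dio3 cluster, held 3.54% ± 0.359 from 49 detected genes. The liver miRNA Mir122 had 166 and 171 counts, or 41.4 ± 4.36 CPM.

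Mir1a-1, Mir1b, Mir133a-1, Mir133a-2 and Mir133b summed to 11.4 ± 0.791 CPM, while myosin-hosted Mir208b alone reached 66568 ± 359. Within 14 shared-transcript clusters, members sharing 20 bases with another hairpin lay below their neighbours by a mean log2 difference of -3.88 ± 3.50 (SD over clusters, permutation within clusters, two-sided, p = 0.00163), in 13 of 14 clusters. A candidate explanation is that reads of near-identical loci went to the class mapping to several places, although Mir23a and Mir23b share such a stretch and were abundant. Low transcription of these loci cannot be told apart from this, because that class held 0.574 reads per assigned read, not split by miRNA. The design has 1 group, so no biological explanation was tested.

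The epithelial list, including Mir205, Mir200c and Mir429, was higher in replicate 2 by a median log2 ratio of 1.15. Scaling did not account for this, since the lower median of TMM and median-of-ratios scaling was 1.04. The pooled list was 1.78-fold higher with a lower 95% bound of 1.70, more than counting error of independent reads would give. Reads are not independent molecules, so chance from sampling few molecules was not excluded. More tissue of epithelial origin in the replicate 2 sample may contribute but was not settled: a further list of 10 epithelial miRNAs had a median of 0.18 at percentile 64.9, with 7 of 8 compared members higher. In it Mir449a was higher by 1.38 on the log2 scale, whereas its most abundant members Mir34c (429 and 457 CPM) and Mir224 (248 and 279 CPM) differed little, and Mir184 was lower (28.7 and 23.2 CPM). The 10 members of the main list come from few transcripts and are not independent. Mir137, Mir7b, Mir206 and Mir375 of other lists were also higher in replicate 2, although the neuronal list as a whole lay at percentile 46.1. Collection day remains an open explanation.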
